A study of Mus musculus with 16 samples.

How the data were processed

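RNA of the nucleus accumbens of male C57BL/6 mice, aged 5 months, was profiled on 16 single-colour Illumina bead arrays, per the labels. Mice received saline or S-adenosylmethionine (SAM, the methyl donor of most cellular methylation reactions) and, 20 minutes later, saline or cocaine at 10 mg/kg, on 7 days, and tissue was taken 24 hours after the last treatment. Each of the 4 groups had 4 samples, and 2 tissues were combined in each sample, per the labels. The labels do not say how many mice those tissues came from, so p-values of single genes measure the spread between these samples, part of which may be technical.

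The authors' deposited raw table holds, for 25697 probes and each array, a linear intensity and a detection p-value. Per the file headers these intensities are not normalized. The values show that background had been subtracted, since 23.4% to 26.2% of each array's intensities lie below 0. BeadStudio, R 2.13.0 and limma are named in the submitters' processing notes, with no role stated. The authors' deposited normalized table holds linear intensities with array medians of 29.2 to 29.3 and a rank correlation of 1.0 with the matching raw columns. Its method of normalization is not given in the sources used here, and it served as an alternative. Among the raw values, 179 of 411152 intensities (0.044%) were damaged: 167 were not numbers, and 12 lay off the curve that ties an array's raw to its normalized values. These were restored from that curve. Symbols were updated through RefSeq accessions for 23739 probes (92.4%), of which 3903 received another symbol, and 1958 probes kept the symbol of the file.

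From the raw intensities, values were quantile normalized between arrays, floored at 1, raised by an offset of 16 and taken to log2 with limma 3.58.1 in R 4.3.3. The design fixed before the data were examined used background correction with neqc only for values that were not yet corrected, so that step was left out and neqc was run as an added alternative. As a result, the comparison fixed in advance with quantile normalization without background correction coincides with the processing used. Probes with a detection p under 0.05 on at least 4 of 16 arrays were kept, 14258 in number, and for each of 10612 genes the probe with the highest mean was tested. The offset shrinks the fold changes of dim probes. Where a gene was not above background on any array of a group, its fold change is given as a bound, "at least N-fold", of the brighter group's mean against the higher of the dim group's signal and the lowest detected signal, and without a bound where that ratio was under 1 or both groups were dim. Such a bound describes the measured means only. It carries no sampling error, so it does not establish a difference for a gene that did not pass the threshold.

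Samples of a group were compared before averaging. Of 6852 genes detected at p under 0.01 on all arrays, the 340 most variable (5% within each of 20 level bins) were set against the 3432 least variable (50%). A pair whose median absolute difference over the variable genes was under 1.25 times that over the stable genes, and below that of every pair from different groups, differed by no more than array noise and was counted as 1 sample. The reference genes, the bound of 1.25 and the exclusion of 2 noisy arrays from this judgement were set after the values were seen, and the fixed design had named 16 separate samples. The fit therefore held 13 samples: 4 for saline, 4 for SAM, 3 for cocaine and 2 for SAM plus cocaine. Counting every sample was run as an added alternative.

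One mean per group was fitted with limma (lmFit and eBayes, two-sided), with 1 estimate of spread shared by all groups, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 pairwise comparisons, the interaction and both average effects were tested. Every adjusted p of a gene is limma's. The unmoderated fit used the same shared spread, which 2 noisy arrays raise, so its counts of 0 give no separate support. At an unadjusted p under 0.05, chance gives 530.6 genes in each comparison. For 30 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01, and again with an estimated correlation, and fry was run beside it. With the preset correlation, camera's p rests on the spread between genes and not between samples. An exact permutation of samples was run on the list scores in the 5 pairwise comparisons and called 0 lists in each. Unadjusted, 1 list had p under 0.05, in SAM against saline. With 2 samples of SAM plus cocaine, this test could not reach 0.05 in comparisons of that group. Camera asks whether a list moved relative to the other genes, so its direction can differ from the sign of the median or mean: these differed for 10 of 30 lists in cocaine against saline, 15 in SAM against saline, 8, 6 and 5 for SAM plus cocaine against saline, cocaine and SAM, and 7 in the interaction, with none among the lists called by camera. The named genes are those past the threshold or, where fewer than 20 passed, the genes with the smallest p until 20 were named, with up to 4 members of each list discussed and Dnmt1, Dnmt3a, Dnmt3b, Ppp1cb, Fosb, Fos, Cck and Mat2a in every case. Some genes that this rule takes are not reported here. Of the 120 named by p, 20 had other probes past the filter, and for 13 of these all of the other probes had the same sign.

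Before use, the fit was tested on simulated data with 200 changed genes among 10612. Values were drawn independently for each gene, with the same residual SD on every array. The simulation thus left out the raised spread of 2 arrays and any dependence between genes. Its rates may therefore not hold for the measured data. The myelin list was also lowered by 0.5, and its called members are in the call totals. For cocaine against saline the fit recovered 3% of genes changed by 0.5 on the log2 scale, 44.8% of those changed by 1 and 74.2% of those changed by 2. For SAM against saline the shares were 9%, 46.3% and 86.4%. For SAM plus cocaine they were 1.5%, 32.8% and 72.7% against saline, 0%, 32.8% and 78.8% against cocaine, and 4.5%, 29.9% and 72.7% against SAM. Without the 2 arrays that stand apart they were 46.3%, 89.6% and 100% for cocaine against saline, 40.3%, 79.1% and 98.5% for SAM against saline, and 26.9% to 41.8%, 74.6% to 88.1% and 97% to 98.5% for SAM plus cocaine. False calls were 5 to 9 of 77 to 100 calls with all samples and 4 to 11 of 150 to 175 without the 2. The number of arrays and the spread of 2 of them limit the precision: the simulation's median residual SD was 0.353 over all samples and 0.152 without the 2 arrays that stand apart.

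Other settings fixed in advance covered the normalization, the offset, the detection filter, the choice of probe, the authors' normalized values, array quality weights, other forms of the fit, the threshold, the set test, the replicate number as a block and each sample left out. Settings added after the data were seen were neqc, other treatments of the repeated and noisy arrays, and a regional marker score as a covariate. Slides are not named in the sources used here, so slide was not used as a block. The labels number all samples without cocaine before all samples with cocaine. A slide or run that followed this order could not be told apart from cocaine. Dnmt3a was not tested because neither of its probes was detected on any array.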

Results

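Gene expression in the nucleus accumbens, the ventral striatal region that receives midbrain dopamine, was measured in 16 samples after 7 days of saline, SAM, cocaine or both. The comparisons ask what repeated cocaine does to expression in this tissue and whether a methyl donor given before each injection alters that response. Between 48.4% and 54.4% of probes were detected per array. The median background-subtracted intensity was 9.9 on replicate 1 of the saline group and 21.3 to 36.5 on the other arrays. The median rank correlation with the other arrays was 0.865 for that sample, 0.942 for replicate 4 of the SAM group, and 0.974 to 0.979 for the remaining 14.

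**Figure D1:**
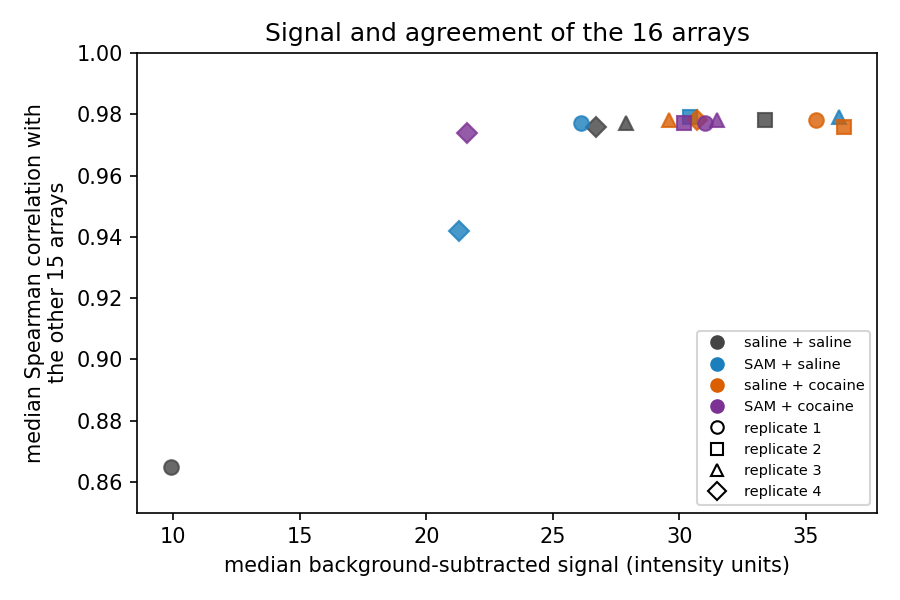
Median background-subtracted signal (intensity units, x axis) against the median Spearman correlation with the other 15 arrays (y axis), with 1 point per array, coloured by group and shaped by replicate. Replicate 1 of the saline group lies at 9.9 and 0.865, and replicate 4 of the SAM group lies at 0.942, below the other 14 arrays.

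Of the samples, 3 pairs differed by no more than array noise and were counted as 1 sample each. Replicates 1 and 2 of the cocaine group had a median absolute log2 difference of 0.09 over variable genes and 0.08 over stable genes. The differences were 0.08 and 0.08 for replicates 1 and 3 of the SAM plus cocaine group, and 0.11 and 0.10 for its replicates 2 and 4. In the same order, deviations of the 2 samples over variable genes had rank correlations of 0.894, 0.761 and 0.625. The highest for a pair from different groups was 0.645, so by this measure the last pair did not stand out. Other pairs of the cocaine group had ratios of variable to stable differences of 2.547 to 3.245, and other pairs of the SAM plus cocaine group had ratios of 1.258 to 1.473, close to the bound used. Some of the latter lay below the lowest ratio of a pair from different groups without a noisy array (1.395). Every pair of the SAM plus cocaine group differed by at most 0.153, less than any pair from different groups. Whether the 2 samples counted in this group are independent therefore stays open. Samples of different groups differed by at least 0.20. Replicates 2 and 4 of the SAM group had a ratio of 0.93 at a difference of 0.16, on an array with raised noise, and stayed separate.

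**Figure D2:**
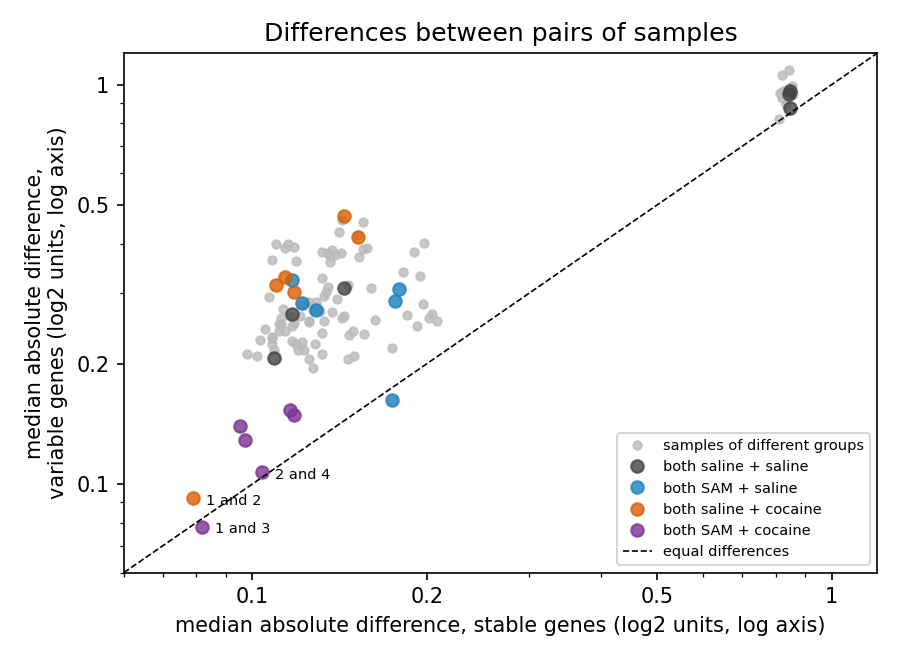
Median absolute log2 difference of each pair of samples over 3432 stable genes (x axis, log scale) and over 340 variable genes (y axis, log scale), with pairs of 1 group in colour, pairs from different groups in grey and equal differences as a dashed line. The 3 annotated pairs, named by replicate number, lie at or near the line below 0.11, while pairs from different groups lie at 0.195 or above.

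Regional markers separated samples within groups. The mean of 17 cortical glutamatergic neuron markers, centred on all samples, was -1.255 and -1.203 in replicates 1 and 2 of the cocaine group and between -0.21 and 0.57 in the other 14 samples. The mean of 20 septal, hypothalamic and thalamic markers was 0.73 in both of these samples and at most 0.48 elsewhere. Slc17a7, the vesicular glutamate transporter of cortical neurons, had log2 signals of 7.50 and 7.53 in them and 11.15 to 12.62 elsewhere. Oxt, which encodes oxytocin, had 10.93 and 10.86 there and 4.97 to 8.86 elsewhere, and Gal, which encodes galanin, had 11.19 and 11.20 there and 5.78 to 10.13 elsewhere.

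**Figure D3:**
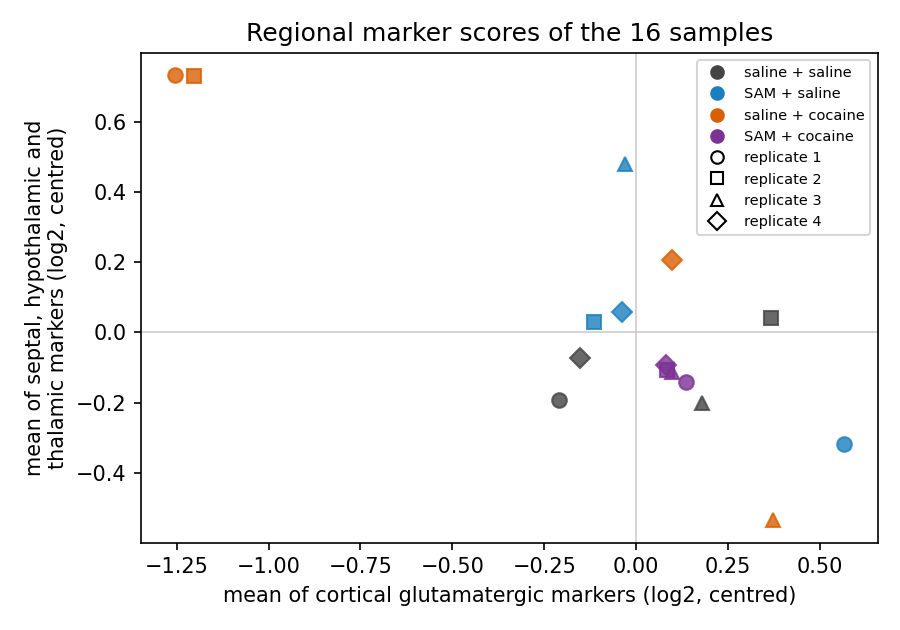
Mean of the cortical glutamatergic markers (x axis, log2, centred) and of the septal, hypothalamic and thalamic markers (y axis, log2, centred) in each of the 16 samples, coloured by group and shaped by replicate. Replicates 1 and 2 of the cocaine group lie at the upper left, at -1.255 and 0.734 and at -1.203 and 0.731.

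None of the genes chosen in advance and reported here passed the threshold between groups by limma. Dnmt1, the maintenance DNA methyltransferase, had a log2 signal of 7.68 ± 1.54 (SD, n = 4) with saline, 8.79 ± 0.14 (SD, n = 4) with SAM, 8.77 ± 0.20 (SD, n = 3) with cocaine and 8.50 ± 0.04 (SD, n = 2) with both. Fos, an activity-induced transcription factor, had 8.68 ± 1.83, 9.25 ± 0.53, 9.57 ± 0.40 and 9.54 ± 0.57 in the same order, and Fosb had 7.72 ± 1.81, 8.33 ± 0.13, 8.31 ± 0.30 and 8.53 ± 0.03. Mat2a, a subunit of the enzyme that makes SAM, had 11.87 ± 0.21, 11.93 ± 0.07, 11.97 ± 0.08 and 12.05 ± 0.04. Ppp1cb, a catalytic subunit of protein phosphatase 1, had 9.32 ± 0.79, 9.59 ± 0.22, 9.51 ± 0.02 and 9.69 ± 0.35. In the 2 cocaine-treated groups the SD is taken over values that include means of repeated arrays, which can lower it. The arrays of the cocaine group had 9.37, 9.69, 9.49 and 9.52 for Ppp1cb. Cck, which encodes cholecystokinin, had 10.40 ± 0.68, 10.67 ± 0.54, 10.10 ± 1.46 and 10.50 ± 0.03. Dnmt3b had 5.37 ± 0.27, 5.65 ± 0.11, 5.42 ± 0.17 and 5.45 ± 0.12. Its probe was detected on 12 of 16 arrays, so these values lie near background, where the offset shrinks differences. Much of the spread with saline came from replicate 1, where Dnmt1 was 5.39 and Fosb 5.01. Without that array and replicate 4 of the SAM group, the log2 fold change of Dnmt1 was 0.33 for cocaine against saline and 0.28 for SAM against saline, in place of 1.09 and 1.12. It was -0.32 and -0.35 for Fosb, in place of 0.58 and 0.61, 0.04 and -0.17 for Fos, in place of 0.90 and 0.57, and -0.18 and -0.21 for Ppp1cb, in place of 0.20 and 0.27. Mat2a had 0.003 and -0.01, in place of 0.10 and 0.05, Dnmt3b had -0.08 and 0.12, in place of 0.05 and 0.28, and Cck had -0.56 and 0.12, in place of -0.30 and 0.27. Without both replicates 1 and 2 of the cocaine group, Cck had 0.55 for cocaine against saline.

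**Figure D4:**
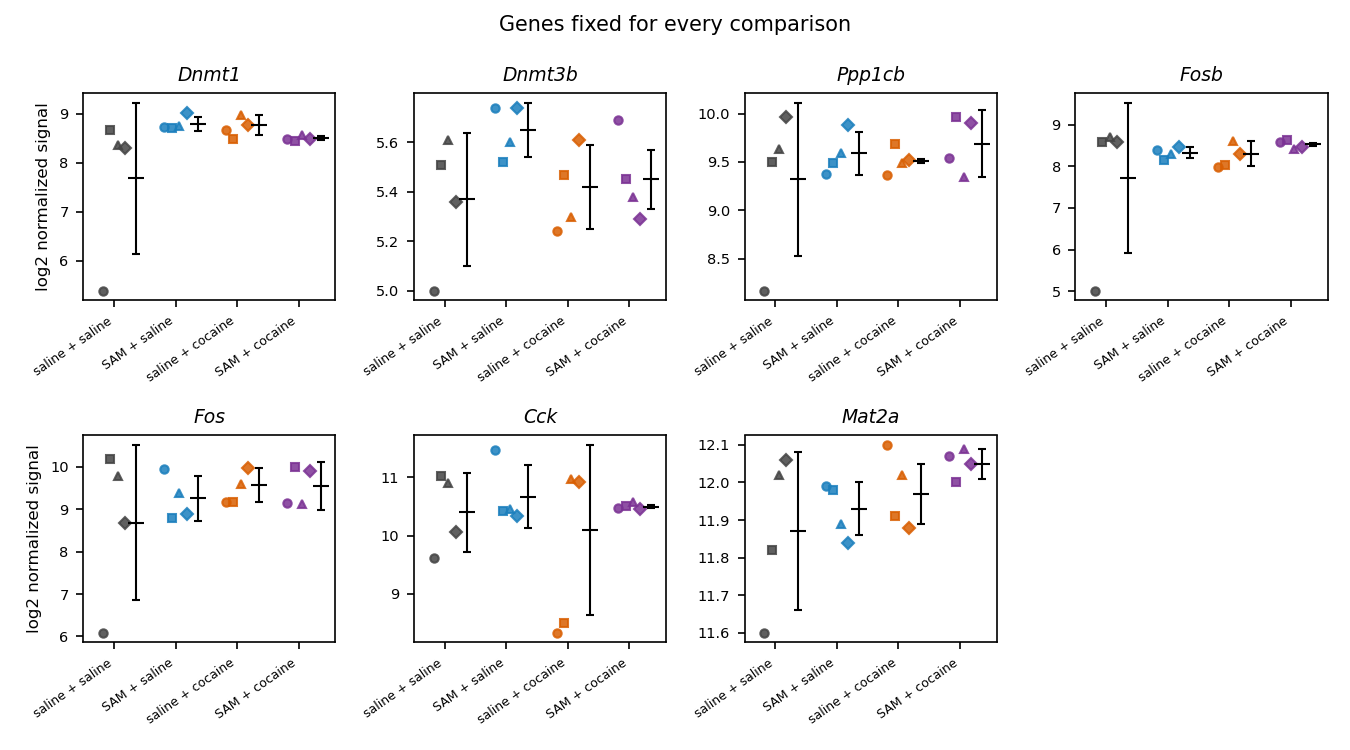
Log2 normalized signal (y axis) of 7 genes in each sample, coloured by group and shaped by replicate, with a black bar for the group mean and whiskers for the SD after repeated samples were counted once. Replicate 1 of the saline group lies lowest in its group for all 7 genes, with Dnmt1 at 5.39 and Fosb at 5.01.

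With cocaine against saline, no single gene and no gene list passed the threshold. Log2 fold changes were 0.71 (SE 0.19) for Pnpla6, a neuronal lysophospholipase, 0.77 (SE 0.21) for the kinase Wnk2, 0.74 (SE 0.21) for the neural adhesion molecule L1cam, 0.43 (SE 0.12) for the RNA-binding protein Tardbp and -0.99 (SE 0.28) for the alpha globin Hba-a1, whose probe may also read its near-identical copy. They were 0.99 for 1700003F12Rik, 0.55 for Srpr, 1.17 for Dhrs13, 0.82 for Ccne1, 0.89 for Dock9, 0.59 for Pkdcc, -0.81 for Ptges3l, -0.90 for Ecrg4 and -0.78 for Crygn. With saline not above background, the signal with cocaine was at least 1.05-fold higher for the potassium channel Kcna10, 1.21-fold for the glycan-branching enzyme Mgat5, 1.07-fold for Ttc24, 1.11-fold for Utrn and 1.08-fold for the natural killer receptor Klrb1c, and Prxl2c, not above background with cocaine, was at least 1.18-fold lower. By limma 0 of 10612 genes passed, with a smallest adjusted p of 0.665, and an unmoderated fit of the same model also called 0. At an unadjusted p under 0.05 there were 459 genes (278 higher, 181 lower), where chance gives 530.6.

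Median log2 fold changes of the lists with cocaine were -0.23 for cortical glutamatergic markers (14 of 17 lower) and 0.31 for septal, hypothalamic and thalamic markers (12 of 20 higher). They were 0.23 for D1-type, -0.36 for D2-type and -0.16 for pan medium spiny neuron markers, -0.09 for striatal interneuron markers and -0.16 for dopamine signalling. For enzymes and regulators of methylation the medians were 0.05 for the DNA methylation machinery, 0.05 for the methionine cycle, -0.33 for SAM-dependent methyltransferases and polyamine synthesis and 0.02 for histone modifying enzymes. Medians for signalling lists were -0.03 for immediate early genes, -0.06 for glutamate receptors, 0.10 for the inhibitory synapse, 0.16 for neuropeptides, -0.08 for cocaine-response regulators, -0.02 for adenosine signalling, 0.12 for glucocorticoid-responsive genes and 0.36 for the circadian clock. Medians for cell state and other cell types were 0.31 for heat shock, 0.19 for interferon response, -0.01 for oxidative phosphorylation, 0.02 for ribosomal proteins, 0.14 for myelin, -0.19 for oligodendrocyte precursors, 0.02 for astrocytes, -0.30 for microglia, 0.09 for endothelium, -0.03 for blood and 0.08 for choroid plexus. Leaving out replicate 1 of the saline group gave 12 of the 30 medians the other sign, those for the DNA methylation machinery (-0.06), interferon response (-0.03), D1-type markers (-0.06), striatal interneurons (0.09), oligodendrocyte precursors (0.09), glucocorticoid-responsive genes (-0.05), glutamate receptors (0.03), cocaine-response regulators (0.02), adenosine signalling (0.005), ribosomal proteins (-0.008), astrocytes (-0.05) and myelin (-0.04). Other medians that moved by over 1.5 times were then -0.54 for blood, 0.04 for heat shock, 0.05 for the circadian clock, -0.09 for SAM-dependent methyltransferases, -0.17 for D2-type and -0.08 for pan medium spiny neuron markers, -0.02 for dopamine signalling, -0.04 for microglia, 0.005 for endothelium, 0.06 for neuropeptides, 0.06 for the inhibitory synapse, -0.06 for immediate early genes, -0.06 for oxidative phosphorylation and 0.01 for histone modifying enzymes. Camera called 0 of 30 lists with a smallest adjusted p of 0.0832, and fry called 0. Without replicate 3 of the cocaine group camera called 4 lists, cortical (adjusted p = 0.000213), pan medium spiny (0.000385) and D2-type (0.0207) markers lower and septal, hypothalamic and thalamic markers higher (0.0214). It called blood (2.3e-05) and cortical (0.0276) markers, both lower, without replicate 1 of the saline group, and without replicate 4 of the cocaine group it called 1 list. It called the methyltransferase and polyamine list lower (median -0.31, adjusted p = 0.0223) without both replicates 1 and 2 of the cocaine group, a setting chosen after the data were seen. Adjusted over the list alone, 2 blood genes were called, Hba-a1 and Alas2 (-0.72), and 1 choroid plexus gene, Ecrg4. Without replicate 1 of the saline group and replicate 4 of the SAM group, a setting chosen after the data were seen, limma still called 0 genes, with 1267 at an unadjusted p under 0.05, and called 36 when repeated samples were counted separately.

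With SAM against saline, no single gene passed. Camera called 2 lists lower relative to other genes: D2-type medium spiny neuron markers, and SAM-dependent small-molecule methyltransferases with polyamine enzymes. D2-type markers had a median log2 fold change of -0.46, with 8 of 9 lower (camera adjusted p = 0.0463). This call was lost with an estimated correlation (adjusted p = 0.768). Its leading members were the receptor phosphatase Ptprm (-0.48), the transcription factor Sp9 (-0.89), Plxdc1 (-0.93), whose probe was among those lost on replicate 4 of the SAM group, and the adenosine receptor Adora2a (-0.93). Without that array and replicate 1 of the saline group, the list had a median of -0.21, and these values were -0.32 for Ptprm, -0.24 for Sp9, 0.19 for Plxdc1 and -0.10 for Adora2a. The methyltransferase list had a median of -0.21, with 10 of 13 lower (camera adjusted p = 0.0463, and adjusted p = 0.768 with an estimated correlation), led by the decarboxylase Amd2 (-0.43), the arsenite methyltransferase As3mt (-0.58), spermidine synthase Srm (-0.85) and Inmt (-0.39). Without the same 2 arrays its median was -0.02, with -0.35 for Amd2, -0.30 for As3mt, -0.24 for Srm and -0.15 for Inmt. Both calls ended without replicate 1 of the saline group (adjusted p = 0.317 for the methyltransferase list and 0.215 for D2-type markers), and leaving out replicate 3 or 4 of the saline group, or 3 or 4 of the SAM group, also ended both, at 0.0501 to 0.123. On replicate 1 of the saline group the methyltransferase score was 0.63, against -0.02 to 0.03 on the other arrays of that group. With cocaine against saline the medians were also below 0, at -0.33 for the methyltransferase list and -0.36 for D2-type markers. These falls were thus not particular to SAM. Camera called 2 other lists without replicate 1 of the saline group, oxidative phosphorylation (0.00452) and blood (0.0107), both lower. The methyltransferase call ended as well without replicate 2 of the saline group (0.0515) or replicate 2 of the SAM group (0.107). Over 18 settings other than leaving out 1 sample, the methyltransferase call held in 9 and the D2-type call in 11.

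Single genes with SAM gave 0 of 10612 past the threshold by limma, a smallest adjusted p of 0.608 and 604 genes at an unadjusted p under 0.05 (455 higher, 149 lower). An unmoderated fit called 0. In the fit without replicate 1 of the saline group and replicate 4 of the SAM group limma called 0, with 946 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0762. Log2 fold changes were 0.73 (SE 0.14) for Celsr3, a cadherin of axon guidance, 1.46 (SE 0.32) for the neuronal adhesion molecule Negr1, 0.77 (SE 0.18) for Pnpla6, 0.74 (SE 0.19) for Wnk2, -2.09 (SE 0.50) for Ctcfl, a paralogue of the chromatin factor CTCF, and -1.41 (SE 0.30) for Gemin2, which assembles splicing particles and whose second probe had the other sign. Positive values also belonged to 5830427D03Rik (0.93), 2610020C11Rik (1.40), the small nucleolar RNA Snora65 (0.87), Snhg11 (1.28), 1110059G10Rik (0.60), 6430411K18Rik (1.31), Rgl2 (0.74), Rnpepl1 (0.63) and the ciliary transport gene Ift172 (0.46). Negative values belonged to the ubiquitin ligase Rnf114 (-0.59) and Btg3 (-0.68). With saline not above background, Xntrpc was at least 1.36-fold and Cep95 at least 1.2-fold higher with SAM. Among the DNA methylation machinery 12 of 17 members were higher (median 0.18, camera adjusted p = 0.738), with Uhrf2 at 0.34 and Zbtb38 at 0.83. Without replicate 1 of the saline group and replicate 4 of the SAM group, a setting chosen after the data were seen, values were -1.248 for Ctcfl, 0.85 for 2610020C11Rik, 0.47 for Rgl2, 0.47 for Wnk2, 0.38 for Rnpepl1, 0.21 for Uhrf2 and 0.28 for Zbtb38, and the methylation machinery had a median of 0.02. With no detection filter limma called 1 gene.

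With SAM plus cocaine against saline, no single gene passed. Camera called microglia and macrophage markers and the methyltransferase and polyamine list lower relative to other genes. The microglial list had a median log2 fold change of -0.26, with 14 of 23 lower (camera adjusted p = 0.0175), and was lost with an estimated correlation (adjusted p = 0.578). It was led by the Fc receptor subunit Fcer1g (-0.69), the complement gene C1qc (-0.44), the purine receptor P2ry13 (-0.71) and Fcgr3 (-0.56). The methyltransferase list had a median of -0.25, with 12 of 13 lower (camera adjusted p = 0.0175, and adjusted p = 0.942 with an estimated correlation), led by As3mt (-0.54), Pemt (-0.48), Mtap (-0.36) and Amd2 (-0.27). Without replicate 1 of the saline group the methyltransferase call ended (adjusted p = 0.278), as it did without replicate 4 of that group (0.0640) or replicate 2 of the SAM plus cocaine group (0.0570), and the microglial call ended without replicate 4 of the saline group (0.138). Leaving out replicate 1 of the saline group also brought 4 other calls, all lower: myelin (0.00676), ribosomal proteins (0.00800), blood (0.0149) and interferon response (0.0185). Both calls ended without both replicates 1 and 3 of the SAM plus cocaine group (0.107), a setting chosen after the data were seen, which leaves 1 sample in that group. Values without replicate 1 of the saline group and replicate 4 of the SAM group were -0.38 for Fcer1g, -0.27 for C1qc, -0.34 for P2ry13, -0.32 for Fcgr3, -0.28 for As3mt, -0.18 for Pemt, -0.18 for Mtap and -0.14 for Amd2.

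Of single genes with SAM plus cocaine against saline, 0 of 10612 passed by limma (smallest adjusted p 0.807), 202 had an unadjusted p under 0.05 (126 higher, 76 lower), and an unmoderated fit called 0. With replicate 1 of the saline group and replicate 4 of the SAM group left out limma called 0, with 836 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.413. Log2 fold changes were 0.69 (SE 0.20) for Rab1a, a GTPase of transport from the endoplasmic reticulum, 0.50 (SE 0.14) for Srpr, 0.86 (SE 0.24) for 1700003F12Rik, -0.78 for Ly6g6d, 0.61 for Zfp566, 0.71 for Rnf112, 0.65 for Tmprss13, 0.46 for the kinase Bmx, 0.83 for LOC100045304 and 0.73 for the potassium channel subunit Kcnab3. With saline not above background, the signal was at least 1.23-fold higher for Olfr497 (whose family members share sequence), 1.01-fold for Kcna10, 1.37-fold for the collagen Col11a2, 1.29-fold for the calcium channel Trpv5, 1.14-fold for Tm4sf20 and 1.15-fold for Cdca5. Genes not above background with both treatments were Kcnmb1, at least 1.21-fold lower, Mmp23, at least 1.05-fold lower, and Ch25h and Rbm47, for which no bound could be set. With array quality weights limma called 12 genes, 11 higher and 1 lower, among them Kcna10, Col11a2, Olfr497, Srpr and Bmx, and with no detection filter it called 7.

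With SAM plus cocaine against cocaine, no single gene passed, and camera with the preset correlation called 9 of 30 lists as moved relative to other genes. Fry called 0 of them. The exact permutation of samples also called 0, though with 10 assignments it could not reach 0.05. Higher lists were cortical glutamatergic markers (median log2 fold change 0.23, 15 of 17 higher, camera adjusted p = 1.0e-05), immediate early genes (0.11, 24 of 31, 0.00881), pan medium spiny neuron markers (0.13, 22 of 25, 0.00613), D1-type markers (0.21, 7 of 11, 0.0402) and blood cell markers (0.20, 5 of 7, 0.0179). Lower lists were interferon response (-0.21, 11 of 13 lower, 0.00349), astrocytes (-0.10, 17 of 20, 0.00613), microglia (-0.13, 21 of 23, 0.00782) and choroid plexus (-0.18, 10 of 13, 0.0110). No call held with an estimated correlation, where the adjusted p was 0.505 for cortical, 0.526 for immediate early, 0.636 for pan medium spiny, 0.477 for D1-type, 0.335 for blood, 0.526 for interferon, 0.335 for astrocyte, 0.335 for microglial and 0.505 for choroid plexus lists. Leading members were Nr4a2 (0.93, held by both the cortical and the immediate early lists), Slc17a7 (1.09), Tbr1 (0.58), the dopamine signalling protein Ppp1r1b (0.25), the neuropeptide precursor Tac1 (0.35), Drd1 (0.21) and Alas2 (0.47), and, lower, the interferon-induced protease Usp18 (-0.49), Oasl2 (-0.54), the astrocytic transporter Slc4a4 (-0.25), the microglial receptors Cx3cr1 (-0.21) and Csf1r (-0.24 with SE 0.29) and the transthyretin gene Ttr (-0.57). Replicates 1 and 2 of the cocaine group had cortical scores of -1.255 and -1.203. Without both of them, a setting chosen after the data were seen, cortical markers fell with SAM plus cocaine (adjusted p = 0.0149), the interferon (9.0e-08) and microglial (0.00896) lists still fell, endothelial and pericyte markers fell too (median -0.09, 0.00684), and the other 6 calls ended (0.191 to 0.883). In that fit 14 of the 30 medians had the other sign, Slc17a7 (-0.53), Tbr1 (-0.18) and Ttr (0.17) turned sign, and values were 0.13 for Nr4a2, 0.19 for Tac1 and -0.82 for Usp18. With a regional marker score as a covariate, also chosen after the data were seen, camera called 2 lists, interferon response (0.000181) and microglia (0.0228), both lower. Interferon scores in the cocaine group ran from -0.183 to 0.55 (mean 0.083, n = 3, repeats counted once). Those with SAM plus cocaine, -0.14 and -0.101, lay within that range. The interferon call depended on 1 cocaine sample, as given below. The fit without replicates 1 and 2 keeps that sample, so its smaller p does not show that the call is robust.

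Single samples also moved these list calls. Without both replicates 1 and 3 of the SAM plus cocaine group, which were counted as 1 sample, the 3 calls left were those of cortical, immediate early and blood lists, and the other 6 ended (0.0759 to 0.443). Without both replicates 2 and 4 of that group, the immediate early (0.576), D1-type (0.174) and blood (0.424) calls ended, and 4 others appeared: neuropeptides (0.0187), myelin (0.0245) and septal, hypothalamic and thalamic markers (0.0305) lower, and glucocorticoid-responsive genes (0.0208) higher. These 2 settings were chosen after the data were seen. Without replicate 4 of the cocaine group the interferon and astrocyte calls (adjusted p = 0.552 for both), the microglial (0.207), pan medium spiny (0.919) and D1-type (0.235) calls ended. The blood call ended without replicate 3 of the cocaine group (0.167), the immediate early call without replicate 2 of the SAM plus cocaine group (0.0819), and the choroid plexus call without replicate 1 of the saline group (0.0893). The D1-type call ended without that array (0.127), without replicate 2 of the cocaine group (0.0676) and without replicates 2 (0.103) or 3 (0.0929) of the SAM plus cocaine group.

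Of single genes in this comparison, 0 of 10612 passed by limma (smallest adjusted p 1), 10 had an unadjusted p under 0.05 (2 higher, 8 lower), and an unmoderated fit called 0. Leaving out replicate 1 of the saline group and replicate 4 of the SAM group, which enter only the shared spread, gave 0 by limma and 183 at an unadjusted p under 0.05. With these 2 arrays the median residual SD of the fit was 0.353, and without them 0.152. Both counts lie below the 530.6 due by chance. The 0 calls therefore do not show that SAM had no effect in cocaine-treated mice. Log2 fold changes were -0.64 (SE 0.30) for the nuclear receptor Nr2f2, -0.45 for Gm6548, -0.60 for Ncln, -0.48 for the sialic acid receptor Cd33, -0.43 for 3110070M22Rik and -0.52 for Zfp951. They were 0.45 for Cstad, 0.41 for the xylosyltransferase Xylt1, 0.55 for Srp54a, 0.43 for Tnni3k, 0.65 for Krt12, 0.52 for Stard5 and 0.48 for the lactate transporter Slc16a3. Gpcpd1, not above background with cocaine, was at least 1.02-fold higher. Defb1 and Tlr3, not above background with both treatments, were each at least 1.06-fold lower, and Ch25h and Cenpn had no bound there. With no detection filter limma called 6 genes.

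With SAM plus cocaine against SAM, no single gene passed. Camera called D1-type medium spiny neuron markers higher and endothelial and pericyte markers lower, relative to other genes. All 11 measured D1-type markers were higher, with a median log2 fold change of 0.17 (camera adjusted p = 0.0223), and the call was lost with an estimated correlation (adjusted p = 0.630). Without replicate 4 of the SAM group the D1-type median was 0.25 (0.0224) and the vascular median -0.11. They included Tac1 (0.55), which encodes substance P, Ebf1 (0.41) and the dopamine receptor Drd1 (0.18). Of the vascular markers 16 of 19 were lower, with a median of -0.18 (camera adjusted p = 0.0223, and adjusted p = 0.689 with an estimated correlation), led by the endothelial receptor kinase Tie1 (-0.66), Ly6a (-0.64), Higd1b (-0.42) and the pericyte gene Rgs5 (-0.34). The vascular call ended without replicate 1 of the saline group (0.142), replicates 2 (0.117) or 4 (0.159) of the SAM group, or replicates 2 (0.106) or 3 (0.0861) of the SAM plus cocaine group. The D1-type call ended without replicates 1 (0.0527) or 3 (0.0623) of the SAM group, or 2 (0.0587) or 3 (0.0728) of the SAM plus cocaine group. Without both replicates 2 and 4 of the SAM plus cocaine group, a setting chosen after the data were seen, both calls ended. Without both replicates 1 and 3 of that group, chosen likewise, medians were 0.17 for D1-type and -0.26 for vascular markers. Each of these 2 settings leaves 1 sample in that group. Drd1 had 0.31 and Rgs5 -0.13 without replicate 1 of the saline group and replicate 4 of the SAM group.

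Single genes in SAM plus cocaine against SAM gave 0 of 10612 past the threshold by limma (smallest adjusted p 1), 99 at an unadjusted p under 0.05 (32 higher, 67 lower), and 0 by an unmoderated fit. The fit without replicate 1 of the saline group and replicate 4 of the SAM group gave 0 by limma, 764 at an unadjusted p under 0.05 and a smallest adjusted p of 0.532. Log2 fold changes were 0.79 (SE 0.20) for Rab1a, 1.34 (SE 0.37) for Gemin2, whose second probe had the other sign, 0.57 (SE 0.19) for malate dehydrogenase Mdh1, 0.61 (SE 0.19) for the haem enzyme Cpox, -0.43 (SE 0.15) for Drosha, which processes microRNA precursors, and -0.55 (SE 0.18) for Celsr3. They were 0.59 for Ins1, -1.50 for 6430411K18Rik, -0.79 for Xntrpc, -0.49 for Xk, -0.52 for Rbm14, -0.72 for 5830427D03Rik, -0.55 for the corepressor Tle2, -0.69 for Hdhd5 and -0.43 for Ift172. Xylt1, not above background with SAM, was at least 1.30-fold higher with both treatments. Abraxas1, Ascc2 and the fatty acid binding protein Fabp7, not above background with both treatments, were at least 1.12-fold, 1.47-fold and 1.17-fold lower, and Ch25h had no bound. With array quality weights limma called Gemin2 (1.22) and Rab1a (0.80), and with no detection filter it called 6 genes.

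The interaction, which asks whether the cocaine difference with SAM departs from that without it, gave 0 of 10612 genes by limma (smallest adjusted p 0.953), 128 at an unadjusted p under 0.05 (41 higher, 87 lower), and 0 by an unmoderated fit. It gave 0 by limma without replicate 1 of the saline group and replicate 4 of the SAM group too, with 614 at an unadjusted p under 0.05 and a smallest adjusted p of 0.785. Camera called 0 of 30 lists, with a smallest adjusted p of 0.111. That value was shared by 4 lists, among them D2-type markers (median 0.54, 9 of 9 higher) and the methyltransferase list (0.20, 10 of 13 higher). It called 5 lists without replicate 3 of the cocaine group: cortical (adjusted p = 0.000148), pan medium spiny (0.000148), D2-type (0.00502) and immediate early (0.0183) lists higher, and septal, hypothalamic and thalamic markers lower (0.00730). Leaving out replicate 1 of the saline group gave 4 lists, all higher: blood (0.000418), cortical, immediate early and oxidative phosphorylation lists (0.0303 for the last 3). Leaving out replicate 2 of the saline group or replicate 2 of the SAM group gave 2 lists, and leaving out replicates 1 or 4 of the SAM group or 4 of the cocaine group gave 1. In settings chosen after the data were seen, it called interferon and endothelial lists lower (0.0334 for both) without both replicates 1 and 2 of the cocaine group, and D2-type and pan medium spiny markers higher (0.0406 for both) without both replicates 2 and 4 of the SAM plus cocaine group. Interaction values were 1.71 (SE 0.49) for Gemin2, whose second probe had the other sign here too, -1.02 (SE 0.32) for Wnk2, -1.13 (SE 0.37) for the calcium channel Cacna1g, -1.54 (SE 0.52) for Negr1, -0.86 (SE 0.29) for Pnpla6 and 2.29 (SE 0.82) for Ctcfl. Further values were 0.78 for Rnf114, -1.04 for 5830427D03Rik, 0.62 for Kdelr2, -0.58 for Drosha, 0.97 for Srp54a, -0.68 for Celsr3, 0.74 for Cpox, -0.57 for Ift172, 0.79 for Tent2 and 0.71 for Arl6ip5. Serpina3g, Xylt1, Xntrpc and Mgat5 were not above background in at least 1 group. Dnmt1 had an interaction value of -1.39. Without replicate 1 of the saline group and replicate 4 of the SAM group it was -0.56, and that of Ctcfl was 1.45. With no detection filter limma called 2 genes.

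Averaged over SAM, cocaine gave 0 genes by limma (smallest adjusted p 0.867, 312 at an unadjusted p under 0.05), and averaged over cocaine, SAM gave 0 genes (0.963, 66). Without replicate 1 of the saline group and replicate 4 of the SAM group, a setting chosen after the data were seen, both still gave 0 by limma, with 1373 (smallest adjusted p 0.110) and 333 (0.854) at an unadjusted p under 0.05. Microglial markers fell with SAM on average (median -0.22, 15 of 23 lower, camera adjusted p = 0.00821, and adjusted p = 0.383 with an estimated correlation), as did the methyltransferase list (-0.10, 12 of 13 lower, 0.0394, and adjusted p = 0.689 with an estimated correlation). Leaving out replicate 1 of the saline group brought the microglial median to -0.10 (0.000646), and camera then called 5 further lists lower: oxidative phosphorylation (0.00889), astrocytes (0.0111), ribosomal proteins (0.0151), and interferon response and myelin (0.0261 for both). The methyltransferase call ended without that array (0.404), as it did without any 1 of 5 other samples, at 0.0520 to 0.0633. Without both replicates 1 and 3 of the SAM plus cocaine group, a setting chosen after the data were seen, both calls ended (0.0863 for microglia and 0.107 for the methyltransferase list). Without both replicates 1 and 2 of the cocaine group, chosen likewise, the methyltransferase call ended (0.0987). With array quality weights limma called 85 genes for the average effect of cocaine, 59 higher and 26 lower, and with no detection filter 9. The cocaine effects without and with SAM had a correlation of 0.188 across 10612 genes, as high in 3 of 15 assignments of the samples (exact permutation p = 0.2, smallest possible 0.0667). The SAM effects without and with cocaine had a correlation of -0.1, with 8 of 10 assignments as high (exact permutation p = 0.8, smallest possible 0.1). Genes are not independent replicates in these correlations.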

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

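Of the tests in this part, that of an effect of SAM was chosen only after the result was seen. In the saline and SAM groups, the groups with 4 samples, 22 measures were examined for a sample far from the other 3, and 10 of 44 sets held one. Of the measures, 12 were scores of lists that camera had called in these same data, and the measures share arrays. The 2.2 sets that chance would give for measures chosen without the data are therefore no fair yardstick.

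Replicate 1 of the saline group stood far from the others of its group in 4 measures. Its median rank correlation with the other arrays was 0.865 (the others 0.976 to 0.978), its methyltransferase and polyamine score was 0.63 (the others -0.02 to 0.03), and its log2 signals were 5.39 for Dnmt1 (8.29 to 8.67) and 5.01 for Fosb (8.58 to 8.71). Against a tissue piece of another make-up, regional marker genes on this array deviated 0.897 times as far as other genes of the same level, where that ratio was 1.17 to 3.50 on the other arrays, although noise on the array also raises the deviation of those other genes. Noise probe by probe stays open: the deviations of probe pairs of 1 gene had a rank correlation of 0.336 on this array, between the bounds set in advance (0.3 and 0.6) and within the 0.171 to 0.514 of the other arrays. No biological explanation was tested, since the other samples of the group received the same treatment.

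Replicate 4 of the SAM group had a median rank correlation of 0.942 (the others 0.977 to 0.979) and a Dnmt1 signal of 9.01 (8.70 to 8.75). On this array 302 genes lay over 3 log2 units below their level elsewhere, against 239 on replicate 1 of the saline group and at most 1 on any other array. Of 120 other probes of these genes, 7 were lower by over 1 unit on this array, a share of 0.058 that equals the share of all second probes, which is consistent with probes lost on this array. An effect of SAM is argued against by the other 3 samples of the group, where the median deviation of these genes was -0.017.

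Other samples that stood apart are given as values. Replicate 1 of the SAM group had an immediate early gene score of 0.25 (the others -0.13 to -0.08), a cortical score of 0.57 (-0.12 to -0.03) and a Cck signal of 11.48 (10.33 to 10.45). Replicate 2 of the SAM group had an astrocyte score of -0.057 (0.016 to 0.031).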

How the results depend on the processing

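Settings chosen only after the data were seen were neqc, every sample counted, samples left out or averaged in pairs, the marker score as a covariate, and array weights with every sample counted. For the settings that changed a value, the cause was not tested, except that an unadjusted count omits the correction. The planned comparison with quantile normalization without background correction coincides with the processing used, and slide as a block was not run because no slide is named. Signal over background limits the dim genes.

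The 0 genes called in each comparison became 4 (cocaine against saline), 1 (SAM against saline), 7, 6 and 6 (both treatments against saline, cocaine and SAM), 2 (interaction) and 9 (average cocaine) with no detection filter, and 12 and 2 (both against saline and SAM) and 85 (average cocaine) with array quality weights. At an unadjusted p under 0.05 the counts were 459, 604, 202, 10, 99, 128, 312 and 66 (average SAM), and 1267, 946, 836, 183, 764, 614, 1373 and 333 without replicate 1 of the saline group and replicate 4 of the SAM group. By chance 530.6 are due. Without these 2 arrays and with every sample counted, genes called were 36 (cocaine), 5 (both against SAM) and 108 (average cocaine). With array weights and every sample counted they were 1224, 1, 226, 29, 57, 36 and 803, in the order above. All other settings and each of 16 samples left out gave 0 by limma.

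The 17 list calls became 31 with neqc and cyclic loess, 2 with no detection filter, 0 with an estimated correlation, 0 with fry, 29 without the same 2 arrays and every sample counted, 8 without both replicates 1 and 3 of the SAM plus cocaine group, and 10 with the marker score as a covariate. With 1 sample left out they were 11 (without replicate 2 of the SAM plus cocaine group) to 32 (without replicate 3 of the cocaine group), and 29 without replicate 1 of the saline group.

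The correlation of the cocaine effects was 0.083 to 0.225 with 1 sample left out. That of the SAM effects was -0.132 to -0.05. It was -0.215 without the 2 arrays and with every sample counted, -0.197 without them and -0.172 without both replicates 1 and 3 of the SAM plus cocaine group. It was -0.003 without both replicates 1 and 2 of the cocaine group and turned to 0.017 without both replicates 2 and 4 of the SAM plus cocaine group. With the replicate block it was 0.179, and the block called 0 genes in each comparison. Replicate numbers showed no clear pairing: 24 same-number pairs correlated at -0.27 to 0.157 (median -0.0195, 3 over 0.1), and 1 of 16 samples correlated best with its own number. The deviations compared were from group means that include the 2 noisy arrays, so this check could miss a pairing. Between the cocaine and SAM plus cocaine groups, which lack those arrays, same-number pairs were at -0.004 to 0.112 and other pairs at -0.12 to 0.084. Of 3565 values of named genes under other settings, 75 had the other sign and 16 passed the threshold; with 1 sample left out, 32 of 2688 had the other sign. With neqc and median scaling the median log2 fold change of all genes was 0.17, 0.22, 0.13, -0.04, -0.14 and -0.27 in the first 6 comparisons, in place of 0.06, 0.07, 0.06, -0.003, -0.03 and -0.08.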

Other observations

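Of the tests in this part, those of neighbouring regions and of an effect of cocaine, the fits without 2 arrays, the fits with every sample counted and the count of splits by the repeated pair were chosen only after the results were seen.

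With every sample counted and without replicate 1 of the saline group and replicate 4 of the SAM group, limma called 36 genes for cocaine against saline, 28 higher and 8 lower. Lower genes included Ecrg4 (log2 fold change -1.04), a choroid plexus marker, Alas2 (-0.93), the haem synthesis enzyme of red cells, and Mobp (-0.50), a myelin gene. Higher genes included Dhrs13 (0.87), Trappc9 (0.62) and Tardbp (0.47). This setting counts repeated samples as separate, and with repeats averaged it called 0 genes, with a smallest adjusted p of 0.108 and 1267 genes at an unadjusted p under 0.05. Of 35 splits of these samples, 5, the real one included, gave at least the real 36 genes. The highest other gave 368, so chance could not be excluded. Calls came from 7 of the 15 splits that kept replicates 1 and 2 of the cocaine group, which repeat each other, on 1 side. They came from 0 of the 20 splits that parted them. Parting 2 samples that lie far from the rest raises the spread on both sides, so that count of 0 was likely beforehand. In the split with 368, replicates 1, 2 and 4 of the cocaine group stood against the other 4 samples. For SAM plus cocaine against SAM the same setting called 5 genes: Gemin2 (1.19, while in the fit of all samples its second probe had the other sign), Rapgef6 (0.65), Prf1 (-1.16), Rhbdl2 (-0.94) and 2610020C11Rik (-0.76).

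Among 14 samples, without the same 2 arrays, the third principal component held 11.6% of the variance. The 6 samples without cocaine had scores of -12.1 to -3.9 on it, and the 8 cocaine-treated samples, 5 when repeats are counted once, had -0.8 to 9.1. Sample numbers follow the cocaine treatment, so a slide or run in that order could separate them too, and this was not tested. The first component held 27.5%, with 24.1 and 24.3 for replicates 1 and 2 of the cocaine group and -14.8 to 7.5 for the other 12 samples.

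Replicates 1 and 2 of the cocaine group are low in cortical and high in hypothalamic markers. A piece cut with another share of the neighbouring regions, less cortical and more septal or hypothalamic, is a candidate explanation. All 4 of the 2 scores in both samples lay outside the range of the other 14 samples. Oxt, Avp, Gal and Trh were among the raised neuropeptides (Avp at 8.77 and 8.65, Trh at 10.33 and 10.21). The scores are relative and do not show which pieces held neighbouring tissue: Slc17a7 was at 11.15 to 12.62 in the other 14 samples. The markers were fixed in advance, but this test was made on the samples that drew attention to it, and the 2 samples differ by no more than array noise, so they count as 1 case. An effect of cocaine is argued against by the other 6 cocaine-treated samples, whose median cortical score lay above that of the 8 samples without cocaine (difference 0.131). With repeats counted once these are 4 samples, at 0.08 to 0.37, with a difference of 0.141. Only 2 of the 4 received cocaine without SAM. Natural variation between mice was not tested.

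A count of 0 is reached by every split, so splits say nothing about the counts of 0: these were 35 of 35 for the 0 genes called with cocaine against saline (highest other 18), 35 of 35 for its 0 lists (highest other 8) and 35 of 35 for the 0 genes called with SAM against saline (highest other 0). By limma 459 and 604 genes had an unadjusted p under 0.05 there. For the 2 lists called with SAM against saline, 4 of 35 splits gave at least as many (highest other 3), so chance could not be excluded.

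The 3 repeated pairs were counted once or separately. With array quality weights, limma called 1224 genes for cocaine against saline when every sample was counted and 0 when repeats were averaged. The weights were 2.63 and 2.42 for the paired replicates 1 and 2 of the cocaine group when counted separately, against 1.13 for their mean. The labels do not say whether these samples share RNA, and no cause was tested.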
